A study of Homo sapiens with 6 samples.

How the data were processed

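RNA was measured in YCC3, a human gastric cancer cell line, 48 hours after transfection with siRNA against CTNNB1 or with non-targeting control siRNA, on 3 arrays per group. An siRNA is a short double-stranded RNA that directs the cell to degrade a matching mRNA. Per the labels' protocols, 500 ng of total RNA per sample was converted to biotin-labelled sense cDNA and hybridised to an Affymetrix Human Gene ST array, which reads each gene through many short probes summarised into 1 value. The labels call the samples biological replicates. They give no siRNA sequences and do not say whether 1 siRNA or a pool was used. Nor do they say whether the replicates were separate cultures transfected on separate days, so the p-values measure the spread between these 6 samples.

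The deposited values are log2 signals that the authors made with RMA, per the submitters' processing notes, which also name Affymetrix Expression Console 1.1. RMA corrects background, makes the probe distributions of all arrays alike and summarises the probes of a row. The log2 scale was read from the values, which ran from 0.789 to 14.5 with array medians between 5.88 and 5.95. Because the arrays were scaled to a common distribution, a change shared by most genes would not be visible. Scanner intensities were not used here, so background calls per probe are unknown, and the precision is limited by the number of arrays. The genome build and the version of the array annotation used by the authors are not given in the sources used here, and no coordinates are printed.

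The table held 33297 rows. The annotation gave exactly 1 gene symbol for 19460 rows and several symbols for 1754 rows, and 12083 rows were not named in it. Of the rows with 1 symbol, 19429 had a gene ID found in the RefSeq gene table, and no symbol needed an update. For a gene with several rows the brightest row over all 6 arrays was used, which left 18417 genes. No filter on dim genes and no further scaling was applied. All 6 columns of values belonged to the 6 samples.

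Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), CTNNB1 siRNA minus control siRNA, with Benjamini-Hochberg adjustment over all 18417 genes and a threshold of 0.05 on the adjusted p. A gene is said to have risen, fallen or changed only where it passed this threshold. Errors given with log2 changes are standard errors of that fit. The 24 gene lists, written before the data were examined like the tests, the naming rule and most of the other settings tried, were tested with limma's camera, which compares the members of a list with all other genes. Camera was run with its preset correlation between genes of 0.01, with adjustment over the 24 lists, and again with the correlation estimated from the residuals. Called members were counted over all genes tested and adjusted over the list alone.

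The genes named in the text are CTNNB1, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and up to 4 members of each list with the smallest p. Any other gene named was chosen after its values were seen, and is said to be. Histone and ribosomal protein genes have near-identical copies, and signal on their probes can come from more than 1 of them. The same holds for IFNL2 and IFNL3.

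No pair of arrays in a group was identical: the SD of their difference over genes was between 0.203 and 0.262 log2 units. The fit was tested on simulated data for the comparison of CTNNB1 siRNA with control siRNA over 18417 genes, with the real means and spreads and 200 changed genes. It recovered 32.8% of changes of 0.5 log2 units, 92.5% of changes of 1 and all changes of 2, and 3.23% of its calls were unchanged genes. In 20 further draws of independent noise, camera called none of 480 unshifted lists, and it called a list of 22 genes shifted by 0.3 in 20 of 20 draws. These draws hold no correlation between genes, which the real arrays do.

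The other settings were a replicate block, quantile normalization again, median centring, removal of the dimmest 25% or 50% of genes, a trended and robust variance, array weights, a per-gene test without moderation, the mean of all rows of a gene, all rows of the table, a size threshold of 1 log2 unit, a threshold of 0.10, an estimated correlation, the rotation test fry, and leaving out each of the 6 arrays. Cyclic loess scaling and leaving the interferon list out of the list tests were added after seeing the data.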

Results

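Gene expression was profiled in YCC3 gastric cancer cells given siRNA against CTNNB1 (3 arrays) or non-targeting control siRNA (3 arrays), and RNA was taken 48 hours after transfection. CTNNB1 encodes beta-catenin, which links cadherins to the cytoskeleton at cell junctions and acts with TCF/LEF factors as the transcriptional co-activator of the Wnt pathway. The comparison asks which transcripts change when CTNNB1 is silenced. Values are log2 RMA signals for 18417 genes, and array medians over all rows lay between 5.88 and 5.95.

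The targeted transcript was lower in each of the CTNNB1 siRNA arrays than in any control array. CTNNB1 measured 11.84 ± 0.05 (SD, n = 3) with control siRNA and 11.07 ± 0.13 (SD, n = 3) with CTNNB1 siRNA, a log2 change of -0.77 ± 0.10 (SE). This is 41.4% less signal, with a 95% confidence interval of 31.4% to 49.9%, and limma's adjusted p was 0.00267. Its fall was the 36th largest among all genes tested. The fall passed the threshold with any 1 array left out, with log2 changes between -0.84 and -0.71. It did not pass in a per-gene test without moderation, where the adjusted p was 0.199.

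Of 18417 genes, 382 rose and 488 fell, and 3746 had an unadjusted p under 0.05. The large changes were almost all rises: 86 genes rose by at least 1 log2 unit and 8 fell by as much. All 870 called genes had groups that did not overlap, as had 4792 of all genes, where chance gives 10%. The balance of rises and falls depended on scaling, with 43.9% of calls being rises as deposited and 56.3% under cyclic loess. It also depended on single arrays, from 41.5% rises without CTNNB1 siRNA replicate 3 to 67.0% without control replicate 1. The number of called genes was 288 without control replicate 1, 372 without control replicate 3, 283 without CTNNB1 siRNA replicate 1 and 421 without CTNNB1 siRNA replicate 2.

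The genes that rose most were interferon-stimulated genes, which cells switch on in response to interferon or double-stranded RNA. All 38 measured members of the interferon list rose, from 0.60 ± 0.13 (SE) log2 units for ISG20, a gene chosen after its values were seen, to 4.28 ± 0.13 for RSAD2, with a median change of 2.16, or 4.46-fold. RSAD2, which encodes the antiviral enzyme viperin, went from 6.12 ± 0.23 to 10.40 ± 0.15 (SD, n = 3 each), a 19.4-fold rise (limma, adjusted p = 8.49e-08). IFIT1, which binds viral RNA lacking host-type caps, rose 19.3-fold, from 6.09 ± 0.18 to 10.36 ± 0.08 (SD, n = 3 each; limma, adjusted p = 5.44e-08). IFI44L rose from 3.97 ± 0.20 to 7.97 ± 0.15 (SD, n = 3 each), and no fold is given because its control signal was dim and not shown to be above background. OAS2, a double-stranded RNA sensor, rose 15.8-fold and MX2, an antiviral GTPase, 9.96-fold in array signal. The remaining genes among the 12 largest rises were XAF1 (8.92-fold), IFI44 (8.75-fold), IFIT2 (6.95-fold), IFIT3 (6.61-fold), MX1 (6.44-fold), OASL (6.18-fold) and SAMD9 (6.07-fold). Control signals of MX2 (5.50), IFI44 (5.75), IFIT2 (5.21) and IFIT3 (5.37) lay below the array medians and were not shown to be above background either. All 12 belong to the list, as did 29 of the 40 genes with the smallest p. Camera placed the list above other genes with an adjusted p of 4.88e-85, and 0.00762 with an estimated correlation. All 38 members were also called when adjusted over the list alone, and at least 36 were called with any 1 array left out. ISG20 was among those lost, with an adjusted p of 0.114 without control replicate 3.

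Members of the list of Wnt target genes moved in both directions. LGR5, a Wnt-dependent stem cell receptor, showed the largest fall of any gene, from 7.71 ± 0.25 to 6.38 ± 0.28 (SD, n = 3 each), a log2 change of -1.33 ± 0.16 (SE; limma, adjusted p = 0.00173). MYC, a growth-promoting transcription factor, fell by 0.61 ± 0.09 log2 units (adjusted p = 0.00644) and CD44, a cell surface hyaluronan receptor, by 0.57 ± 0.09 (adjusted p = 0.00781). PLAUR, the urokinase receptor, rose by 1.01 ± 0.10 log2 units (adjusted p = 0.000478). The other called members, named after their values were seen, were the feedback inhibitor AXIN2 (-0.58 ± 0.12) and BAMBI (-0.44 ± 0.10), which fell, and the secreted Wnt antagonist DKK1 (0.60 ± 0.12), which rose.

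In all, 5 of the 31 measured Wnt targets fell, 2 rose and 24 did not pass the threshold. Adjusted over the list alone, 6 fell and 4 rose. The list as a whole showed no shared direction apart from other genes: its median change was -0.002 and its mean change -0.06. Camera's adjusted p was 0.461, or 0.541 with an estimated correlation. Camera tests for a shared direction, in which rises and falls offset each other. Whether a larger share of members changed than of all genes, where 870 of 18417 were called, was not tested. Leaving out single arrays ended the calls of CD44 (adjusted p = 0.0507 without control replicate 1), AXIN2 (0.0933 without control replicate 3), BAMBI (0.134 without control replicate 1) and DKK1 (0.0613 without CTNNB1 siRNA replicate 2), which are the highest values for each gene. LGR5, MYC and PLAUR passed with any 1 array left out.

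**Figure D1:**
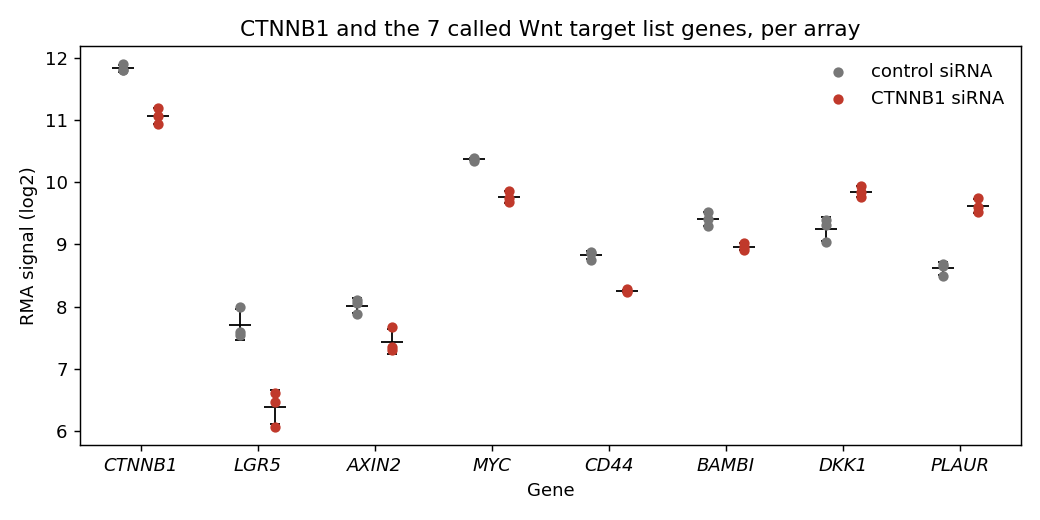
RMA signal on the log2 scale (y axis) of CTNNB1 and the 7 Wnt target list genes past the threshold (x axis), with 1 point per array, grey for control siRNA and red for CTNNB1 siRNA, and bars for the mean ± SD of 3 arrays. CTNNB1, LGR5, AXIN2, MYC, CD44 and BAMBI were lower in all CTNNB1 siRNA arrays than in any control array, and DKK1 and PLAUR were higher.

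Other parts of the Wnt and adhesion machinery showed few changes. Among 34 Wnt pathway components, FZD5, a Wnt receptor, rose by 0.48 ± 0.11 log2 units and TCF7L2, a DNA-binding partner of beta-catenin, by 0.49 ± 0.11, and 32 did not pass the threshold. The co-receptor gene LRP6 measured -0.46 ± 0.12 (adjusted p = 0.0520) and APC, of the beta-catenin destruction complex, -0.40 ± 0.12 (adjusted p = 0.0773). Of 23 catenin, cadherin and desmosome genes only NECTIN2, a junctional adhesion receptor, was called, with a rise of 0.44 ± 0.10. JUP, the close relative of beta-catenin also known as plakoglobin, measured 0.33 ± 0.12 (adjusted p = 0.154). Adjusted over each list alone, 2 pathway components rose and 2 fell, and 1 junction gene rose. Camera's adjusted p was 0.613 for the pathway components and 0.826 for the junction genes. The calls of FZD5, TCF7L2 and NECTIN2 were lost without 1 array or another, with adjusted p of up to 0.121 and 0.146 without CTNNB1 siRNA replicate 1 and 0.144 without control replicate 1.

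Replication-dependent histone genes, which package newly made DNA, fell. Of 19 measured members 14 fell, none rose and 5 did not pass, with a median change of -0.74. Adjusted over the list alone, 16 fell and 1 rose. H3C2 went from 9.56 ± 0.08 to 8.55 ± 0.08 (SD, n = 3 each), with an adjusted p of 0.000291 in limma. H2AC4 went from 8.93 ± 0.10 to 7.83 ± 0.24 (SD, n = 3 each; limma, adjusted p = 0.00128). H2AC13 fell by 0.95 ± 0.12 and H2AC8 by 0.74 ± 0.09 log2 units. H2BC21, chosen after its values were seen, measured 0.58 ± 0.16 (adjusted p = 0.0682). Histone genes made up 6 of the 12 largest falls, with H4C3 at -1.06 ± 0.15, H2BC7 at -0.96 ± 0.19 and H2BC10 at -0.94 ± 0.12. Camera's adjusted p for the list was 7.07e-15, and adjusted p = 0.0843 with an estimated correlation. Probes of these near-identical genes can share signal, so the 14 falls are not 14 independent measurements. The call of H2BC7 was lost without control replicate 1 (adjusted p = 0.0775) or control replicate 3.

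Genes of the cell cycle moved less. In the G1/S and DNA replication list, CCNE2, which encodes the S phase cyclin E2, rose by 0.66 ± 0.12 log2 units (adjusted p = 0.0125) and 39 of 40 members did not pass. Its median change was -0.17, with TYMS at -0.41 ± 0.10 (adjusted p = 0.0538). In the mitosis list, CENPF, a kinetochore protein gene, fell by 0.63 ± 0.14 (adjusted p = 0.0306), 38 of 39 members did not pass, and the median change was -0.10. Counts adjusted over each list alone were the same, 1 gene in each. Camera's adjusted p was 0.00702 and 0.00413, and adjusted p = 0.541 for each list with an estimated correlation. Both list calls were also lost under cyclic loess and under a second quantile normalization. CCNE2 had an adjusted p of 0.0680 and CENPF of 0.135 without control replicate 1.

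The other 5 of the 12 largest falls, apart from LGR5 and the histone genes, were LRP2, ABCC4, SLC12A2, CLGN and ADH1C. LRP2, the endocytic receptor megalin, fell by 1.18 ± 0.11 log2 units (adjusted p = 0.000249), ABCC4, an efflux transporter of cyclic nucleotides and drugs, by 1.08 ± 0.14 (adjusted p = 0.00245), and SLC12A2, the sodium-potassium-chloride cotransporter, by 1.03 ± 0.12 (adjusted p = 0.00168). CLGN, an endoplasmic reticulum chaperone gene, fell by 1.08 ± 0.14, and ADH1C, an alcohol dehydrogenase gene, by 0.97 ± 0.19. The signal of CLGN was dim, at 5.44 ± 0.27 with control siRNA and 4.36 ± 0.11 with CTNNB1 siRNA (SD, n = 3 each), and not shown to be above background. The call of ADH1C was lost without CTNNB1 siRNA replicate 1 (adjusted p = 0.0680).

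Ribosomal protein and proteasome genes lay slightly lower as groups. Of 34 ribosomal protein genes 4 fell and 30 did not pass, with 33 negative changes and a median of -0.27. RPS23 fell by 0.53 ± 0.09 and RPL7 by 0.56 ± 0.12 log2 units. Of 28 proteasome genes only PSMB5, a catalytic subunit, was called, with a fall of 0.55 ± 0.10, and the median was -0.24. In counts adjusted over the list alone, 15 ribosomal protein and 5 proteasome genes fell. Camera gave adjusted p = 4.50e-10 and 1.98e-07, and adjusted p = 0.104 and 0.341 with an estimated correlation. Single arrays ended the calls of RPS23 (adjusted p = 0.0531), RPL7 (0.114) and PSMB5 (0.0853), each highest without control replicate 1.

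The list of endoplasmic reticulum stress and amino acid response genes also lay lower, with 7 of 33 members falling, none rising and a median of -0.19. SEL1L, of the protein degradation machinery of the endoplasmic reticulum, fell by 0.64 ± 0.12 and SHMT2, a mitochondrial serine enzyme gene, by 0.44 ± 0.09 log2 units. Adjusted over the list alone, 12 fell and 1 rose. Camera gave adjusted p = 3.87e-05, and adjusted p = 0.0868 with an estimated correlation. In the oxidative phosphorylation list no gene of 32 was called, also when adjusted over the list alone, and CYC1 measured -0.35 ± 0.09 (adjusted p = 0.0674). In the small RNA machinery list 1 of 13 genes fell, XPO5, the exporter of microRNA precursors, by 0.46 ± 0.11, and 2 fell when adjusted over the list alone. Camera gave adjusted p = 0.00910 and 0.0122 for these lists, and adjusted p = 0.541 and 0.341 with an estimated correlation. The first call was also lost under cyclic loess and a second quantile normalization, and the other without control replicate 1. Without that array the adjusted p was 0.0808 for SEL1L, 0.113 for SHMT2 and 0.168 for XPO5.

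Inflammatory genes and cell death regulators lay higher. In the NF-kB and inflammatory list 4 of 32 genes rose and 28 did not pass, with a median of 0.20. CCL5, a T cell attracting chemokine, rose 4.43-fold (log2 change 2.15 ± 0.14, adjusted p = 1.70e-05) and CXCL8, a neutrophil attracting chemokine, 1.56-fold (adjusted p = 0.0131). Among 27 apoptosis regulators, TNFSF10, the death ligand TRAIL, rose 3.22-fold (adjusted p = 1.28e-05), CASP10 rose 1.48-fold and 25 did not pass. Control signals of CCL5 (5.52) and CASP10 (5.84) lay below the array medians and were not shown to be above background. In all, 12 inflammatory and 4 apoptosis genes rose when adjusted over the list alone. Camera gave adjusted p = 1.09e-06 and 0.00132, and adjusted p = 0.128 and 0.104 with an estimated correlation. CXCL8 had an adjusted p of 0.0645 without control replicate 1 and CASP10 of 0.156 without CTNNB1 siRNA replicate 1, and CASP10 was not called under any other scaling or the replicate block.

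Epithelial, gastric and hypoxia genes lay slightly higher. TFF1, a secreted peptide of gastric surface mucous cells, rose 2.22-fold, from 8.42 ± 0.09 to 9.57 ± 0.17 (SD, n = 3 each; limma, adjusted p = 0.000314), and 3 of 33 gastric and intestinal genes rose. The tight junction gene CLDN4 rose 1.53-fold (adjusted p = 0.00763), and 4 of 30 epithelial genes rose. PFKFB4, a regulator of glycolysis, rose 1.61-fold (adjusted p = 0.00494), and 5 of 29 hypoxia and glycolysis genes rose. No member of these lists fell. Adjusted over the list alone, 5 gastric, 7 epithelial and 7 hypoxia genes rose. List medians were 0.12, 0.19 and 0.14, and camera gave adjusted p = 0.00120, 0.000259 and 3.58e-05 in that order. With an estimated correlation these became adjusted p = 0.270, 0.270 and 0.341.

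The remaining lists held 1 to 3 called genes each. KLF4, a transcription factor of epithelial differentiation and reprogramming, rose 1.90-fold (adjusted p = 0.000865) and JAG1, a Notch ligand, fell by 0.49 ± 0.09 log2 units in the stem cell and efflux list, where ABCC4 also fell and 20 of 23 did not pass. The cell cycle inhibitor CDKN1A rose 1.51-fold and TP53INP1 1.58-fold among 25 p53 targets. MSMO1, a sterol synthesis enzyme gene, rose 1.73-fold (adjusted p = 0.00267) and HMGCS1 1.38-fold among 22 cholesterol synthesis genes. The procoagulant receptor gene F3 rose 1.58-fold and IGFBP3 1.60-fold among 25 YAP and TEAD targets, and ITGA5, a fibronectin receptor subunit, rose 1.65-fold among 34 TGF-beta and mesenchymal genes. Adjusted over the list alone, the counts were 3 higher and 2 lower for stem cell and efflux genes, 4 and 2 for p53 targets, and 5, 3 and 1 higher with none lower for the last 3 lists. Camera's adjusted p for these 5 lists was 0.781, 0.461, 0.281, 0.357 and 0.202. KLF4, ABCC4 and MSMO1 passed with any 1 array left out. The others were lost without at least 1 array, with adjusted p of up to 0.0819 for JAG1, 0.0583 for IGFBP3 and 0.135 for HMGCS1 without control replicate 1, and up to 0.0532 for CDKN1A, 0.0891 for TP53INP1, 0.0544 for F3 and 0.0533 for ITGA5 without CTNNB1 siRNA replicate 1.

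Markers of leukocytes and of endothelial cells and fibroblasts were checked beside these lists. CD68, a lysosomal protein gene used as a macrophage marker, rose 1.93-fold, from 8.98 ± 0.27 to 9.93 ± 0.16 (SD, n = 3 each; adjusted p = 0.00547). None of the other 18 leukocyte markers was called, also when adjusted over the list alone. LYZ, at 12.36 ± 0.04 (SD, n = 3) with control siRNA, had a log2 change of -0.28 ± 0.09 (adjusted p = 0.114). Both CD68 and LYZ were bright already in the control arrays, so their changes alone do not tell of other cells. The list's median change was 0.12, and camera gave adjusted p = 0.0492, and adjusted p = 0.541 with an estimated correlation, and the call was lost in 11 of 17 other settings. None of 20 endothelial and fibroblast markers was called by limma, also when adjusted over the list alone, and camera's adjusted p was 0.145.

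**Figure D2:**
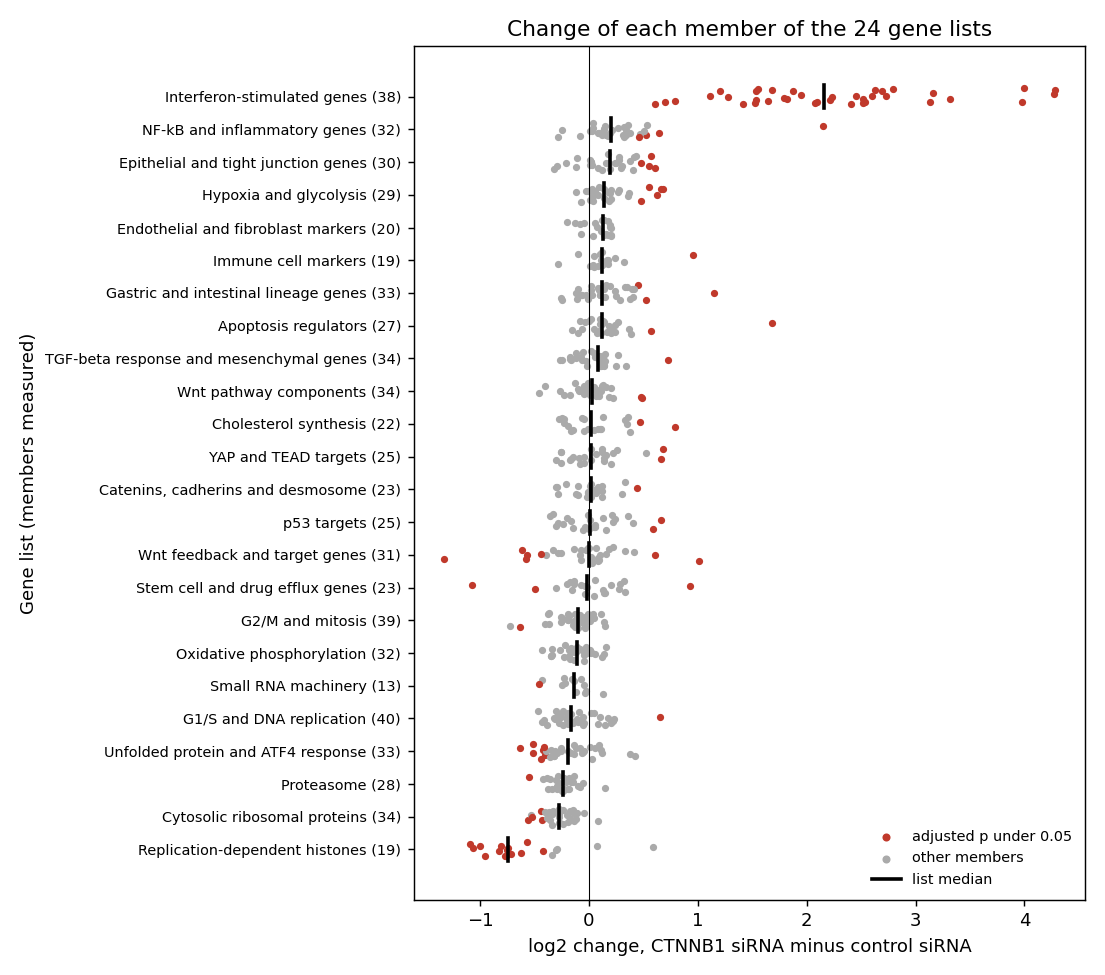
Log2 change, CTNNB1 siRNA minus control siRNA (x axis), of every measured member of the 24 gene lists (y axis, number of members in brackets), with called genes in red, other members in grey and a black bar at the list median. The interferon list lies apart at a median of 2.16, the histone list has the lowest median at -0.74, and the Wnt target list spreads on both sides of 0.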

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

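The tests of leukocyte markers, of S phase genes, of bright Wnt targets and of lists matched for brightness were chosen after the results they measure had been seen, cyclic loess scaling was added after seeing the data, and the other tests in this part were chosen before.

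Rows of the array left out of the gene comparison also passed the threshold in a fit over every row, in both directions. Of the 1754 rows with several gene symbols 12 passed, 9 higher and 3 lower, and the largest rise was 2.77 log2 units on row 8074606. Of the 12083 rows not named in the annotation 32 passed, 20 higher and 12 lower, with a largest rise of 1.40 log2 units on row 8057744 and a change of -2.51 on row 7894600. No gene is named from these rows.

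All 38 interferon-stimulated genes rose. Leukocytes carried into the CTNNB1 siRNA cultures would bring their own abundant transcripts. The 19 leukocyte markers had a median change of 0.12 (bootstrap 95% interval over genes 0.05 to 0.16), with 17 changes positive. CD68 rose 1.93-fold and the other 18 were not called. Camera's adjusted p for the markers was 0.0492, and 0.541 with an estimated correlation. So small a shift beside the 2.16 of the interferon list argues against leukocytes as the source of its rise. Array scaling is argued against too, since array medians over all rows lay between 5.88 and 5.95. The interferon list's median was at least 2.14 under 3 other scalings, but those started from values that RMA had already made alike. The control arrays received non-targeting siRNA, so a reaction common to any transfected siRNA would be present in both groups. A reaction to the CTNNB1 siRNA itself and a response to the loss of CTNNB1 mRNA cannot be told apart here, because the labels name CTNNB1 siRNA only as a single group. Its 3 arrays are too few to relate the list to the remaining CTNNB1 level. Within 1 siRNA group such a relation would not separate these explanations either. Both explanations stay open, and the other changes in the comparison share this limit.

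Histone, ribosomal protein and proteasome genes lay lower with CTNNB1 siRNA, and bright genes as a whole lay slightly lower, with a median change of -0.07 in the brightest 1842 genes and 0.03 in the dimmest. Of 10000 random lists matched to each member's brightness, 0 had a median as low as the -0.74 of histones. The count was 0 for the -0.27 of ribosomal proteins and 13 for the -0.24 of the proteasome. Matched medians were -0.03, -0.06 and -0.07 in that order, so each list lay lower than genes of like brightness. The random lists were drawn gene by gene, while the members vary together. Their estimated correlations were 0.11 for histones, 0.099 for ribosomal proteins and 0.41 for the proteasome. The counts therefore do not measure chance and alone cannot decide whether brightness is the whole cause. Cyclic loess, which removes such a trend, left the histone median at -0.69 (bootstrap 95% interval over genes -0.79 to -0.40). For the histone list this argues against brightness as the whole cause, as does the lowest matched median of -0.26. Cyclic loess left -0.19 for ribosomal proteins (-0.26 to -0.12) and -0.16 for the proteasome (-0.21 to -0.11). Since both intervals reach values under 0.5 of the deposited median, how much of these smaller falls is the trend stays open. Fewer cells in S phase also stays open for the histones, since the G1/S list had a median of -0.17 (interval -0.20 to -0.09) but an adjusted p of 0.541 with an estimated correlation.

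The Wnt target list was not called although CTNNB1 fell by 0.77 log2 units. Dim members could dilute a fall, but the 18 members brighter than the median gene had a median of -0.041 (bootstrap 95% interval over genes -0.42 to 0.09). Their mean was -0.12, and limma's camera did not place them apart from other genes in a shared direction at the 0.05 threshold. The interval includes both a clear fall and none, so this stays open. No biological explanation was tested, and beta-catenin protein was not analysed here.

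Other groupings of the arrays were tried for both counts, but the 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. For genes called, 1 of the 10 splits reached the real value of 870, which was the real one, and the highest other was 0. For lists called by camera with the preset correlation, 1 of the 10 reached 15, again the real one. The other splits, which mix the groups, called 2 to 12 lists each while calling 0 genes. Camera with the preset correlation thus called lists also where the groups were mixed, and its small p-values are to be read with that limit.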

How the results depend on the processing

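The interferon genes tested had a median rise of at least 2.07 in every setting with 1 value per gene. The Wnt list was called under none, with adjusted p between 0.212 and 0.756 and mean changes of -0.12 to -0.03 (-0.08 to -0.03 with an array left out). The fall of CTNNB1 is short of the size threshold of 1. In the settings that fit single genes again it passed in all but the per-gene test without moderation, where the log2 change was -0.77 and the adjusted p 0.199; with an array left out it ranged from -0.84 to -0.71. That test called 1 gene (1 higher, 0 lower), with 2615 at an unadjusted p under 0.05, beside 870 (382 higher, 488 lower) in limma. Leaving out the dimmest 25% gave 1483 (927 lower), the dimmest 50% 1861 (645 higher, 1216 lower), a trended robust variance 1622 (586 higher, 1036 lower), a threshold of 0.10 1668 (660 higher, 1008 lower), testing all rows 252 (179 higher, 73 lower) and a size of at least 1 94 (86 higher, 8 lower). Leaving out single arrays gave 283 to 877 genes, 183 to 364 higher and 95 to 513 lower, fewest lower without control replicate 1. The causes were not tested, beyond the fewer or additional rows and the thresholds that define some of these settings. Cyclic loess, added after seeing the data, called 867 genes, 730 of them among the 870. Deviations of same-numbered samples correlated at -0.02, 0.33 and 0.22. Samples 2 and 3 of each group correlated best with their own number, and sample 1 of each did not. Since not every sample matched, the numbers were not taken to pair the samples, but an effect shared by same-numbered samples stays open. A replicate block called 1177 genes, 845 of them shared, and 15 lists, with CTNNB1 at -0.77. Of the 24 lists 15 were called, 1 with an estimated correlation, and 10 to 15 with an array left out. With an array left out, camera's direction turned for 2 uncalled lists: the mean of stem cell and efflux genes ranged from -0.0219 (without control replicate 2) to 0.0198, with -0.0159 without CTNNB1 siRNA replicate 3, and that of Wnt pathway components from -0.0111 (without CTNNB1 siRNA replicate 1) to 0.0325. Means also turned sign without a turn of camera's direction, for stem cell and efflux genes (lowest -0.0315, without the dimmest 50%) and for catenins, cadherins and desmosome genes (lowest -0.008, without the dimmest 25%). Of 90 other named genes that were called, none changed sign, 48 kept their call in every setting that fits single genes again and included them, but for the unmoderated test (the size threshold of 1 was not applied to them), 5 lost it under another scaling, 2 under the block and 42 without at least 1 array. Dim genes such as CLGN were absent where the dimmest genes were left out, and were not judged there.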

Other observations

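The list of ribosome biogenesis genes was written after the largest falls had been seen, without the members among them, and tested afterwards, while the values of interferon and antigen processing genes were seen before their lists were written, so these 2 lists are given as counts without a group test. Of 8 interferon genes 3 rose and 5 did not pass. The type III interferon genes IFNL1, IFNL2 and IFNL3 rose by 1.16 ± 0.13 (SE), 1.37 ± 0.17 and 0.99 ± 0.19 log2 units (limma, adjusted p = 0.000892, 0.00181 and 0.0186), and IFNL3 lost its call without control replicate 3 (adjusted p = 0.0783). IFNL2 and IFNL3 are near-identical. IFNB1, a type I interferon gene, measured 2.73 ± 0.08 and 3.05 ± 0.27 (SD, n = 3 each), with an adjusted p of 0.226. The type I interferon genes IFNE and IFNK had log2 changes of -0.05 ± 0.10 and -0.07 ± 0.16 (adjusted p = 0.821 and 0.848). Their control means were 2.64 and 2.85, so these genes, like IFNB1, were among the dimmest. At such levels the lack of a call does not tell whether type I interferon genes responded. Of 14 measured MHC class I antigen processing genes 9 rose, none fell and 5 did not pass. The peptide transporter genes TAP1 and TAP2 rose 2.61-fold and 1.66-fold, the class I light chain gene B2M 1.59-fold, and the immunoproteasome subunit genes PSMB9 and PSMB8 3.61-fold and 1.82-fold. The remaining immunoproteasome subunit gene PSMB10 had a log2 change of 0.10 ± 0.13 (adjusted p = 0.710).

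Several of the large falls were in genes of ribosome production, named here after their values were seen. These were POLR1B, a subunit of RNA polymerase I, at -0.87 ± 0.12 log2 units, UTP20 at -0.83 ± 0.12, HEATR1 at -0.78 ± 0.11 and DDX21 at -0.76 ± 0.11. The hypothesis that such genes fell as a group was tested on 89 measured genes of the list. Of these 35 fell, none rose and 54 did not pass. Among the falls, chosen after their values were seen, were RRS1 (-0.74 ± 0.11), DKC1 (-0.68 ± 0.11) and NOP16 (-0.61 ± 0.09). The median of the 89 genes was -0.35 (bootstrap 95% interval over genes -0.42 to -0.31). Camera gave an unadjusted p of 1.25e-28, and of 0.0385 with an estimated correlation. With an estimated correlation, the unadjusted camera p was 0.00703 for the histone list and 0.0216 for the ribosomal protein list. Neither of those lists passed once adjusted (adjusted p = 0.0843 and 0.104). With an estimated correlation p was 0.0182 under a second quantile normalization (median -0.31, 32 falls), 0.0200 under cyclic loess (median -0.30, 25 falls) and 0.0586 under median centring (median -0.37, 33 falls). None of the camera p-values for this list was adjusted over lists. The list was written after genes of the same kind had been seen to fall in these same arrays. Its members also vary together (estimated correlation 0.28), so leaving those genes out does not make the test independent. The p-values therefore cannot decide whether ribosome biogenesis genes fell as a group, which stays a hypothesis. MYC, a known activator of such genes, fell by 0.61 log2 units in the same arrays, and whether the falls are linked was not tested.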
